A study of Mus musculus with 14 samples.

How the data were processed

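The samples were 14 clonal lines of female mouse embryonic stem cells from an F1 cross of the 129 and Castaneus (CAST) strains, in which the parental copies of a gene can be told apart by sequence differences. Each line carries a deletion of an enhancer named Chen2008-1 (8 clones) or Chen2008-25 (6 clones). Polyadenylated RNA was sequenced after hybrid selection, in which a pool of probes enriches the transcripts of chosen genes, per the labels. Cells were grown without serum in medium with leukaemia inhibitory factor and inhibitors of MEK and GSK3, per the labels' protocols.

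The deposited count tables hold, for each clone, whole-number read counts of 472 panel genes in a 129 column and a CAST column, per the file headers. These deposited counts had not been normalized, and reads without an assigned allele were not used here. The genome build was mm9, per the submitters' processing notes, while the aligner, the rule for assigning reads to alleles, the counting tool and its use of strand were not given in the sources used here. Between 78.5% and 88.6% of the counts from 1 to 19 in a clone were even numbers, which is what counting both mates of a fragment gives, so reads are not independent molecules. Of a pair of genes with the same counts in every clone, 1 was left out.

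Genotypes were taken from the deposited genotype table, which holds text of another kind than counts (Het +/-, Het -/+ or KO -/-), per the file headers. The order of the signs is not stated there and was read in the order of the strain name, 129 before CAST. The counts of B3gnt7 bear on this order: in the single -/+ clone of Chen2008-25 the 129 copy was at the level of the KO clones (KO over heterozygous log2 difference -0.02, SE 0.24), while the CAST copy was not (-1.72, SE 0.22). With the other order, every cis value below would change sign. Chen2008-1 had 6 +/- clones (deleted on CAST) and 2 -/+ clones (deleted on 129). Chen2008-25 had 5 KO clones, deleted on both chromosomes, and 1 -/+ clone, E6. No clone was free of both deletions, so the controls at each locus were the clones of the other enhancer. The clone set, the enhancer and a number in the column headers go together (another number, in the sample titles, is the same for all clones, and its meaning is not given in the sources used here), so a difference in level between the sets cannot be separated from the origin or culture of the clones. The hybrid selection batch and the probe set were the same for all clones in the genotype table. All clones come from 1 parental line, and p-values measure the spread between clones of that line.

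Total allelic reads per clone ran from 135881 to 1331960, with a median of 730088 in the Chen2008-1 clones and 573286 in the Chen2008-25 clones. No pair of clones of the same genotype agreed within sampling noise (26 pairs, chi-square per degree of freedom 4.06 to 43.0). Each clone was 1 sample. CPM values are allelic counts scaled by TMM-adjusted library size.

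Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with a mean of at least 10 allelic reads per clone were tested. For the cis effect, edgeR's quasi-likelihood test was run on both allele columns of each clone with terms for clone, allele and allele by direction of the deletion, so that the coefficient is the log2 change of the modified over the unmodified chromosome. Clones deleted on both chromosomes were left out of the cis fit of their own enhancer. The trans effect was tested on the counts of the unmodified allele, and the total effect on the sum of both alleles, with TMM factors computed from totals. The difference between deletions on 129 and on CAST was tested as a contrast of separate terms. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and all intervals are 95% intervals. Shares of a single clone carry Wilson intervals on reads, which cover counting error only and are too narrow even for that where both mates of a fragment were counted.

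These designs, the alternatives in them and the rule for naming genes were chosen before the data were examined. The rule names up to 15 genes past the threshold in the cis test of each enhancer, up to 5 genes past it for each total contrast and each unmodified allele, and the 5 genes of smallest cis p where fewer passed. It also names the measured members of lists of pluripotency, early differentiation, feeder fibroblast, housekeeping, X-linked and imprinted genes. Only the X-linked list had members in the panel (5), and the other lists had 0. A further part of the rule named genes within a set distance of the enhancer. It could not be applied, because positions of the enhancers were not used here, so neighbours were named after their values were seen.

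Chromosomes and the order of panel genes came from the GENCODE annotation of a later mouse build, matched by symbol (428 rows) or older symbol (23 rows). No coordinates are given, since that build is not the one of the counts. Panel genes formed 22 runs of neighbours on 11 chromosomes, with a gap of more than 3 Mb ending a run. Values of some panel genes are not reported here, though they count in the numbers of genes tested.

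The procedures were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. The cis test of Chen2008-1 recovered 89.6% of genes changed 1.5-fold and 92.2% of genes changed 2-fold. The cis test of Chen2008-25, which rests on 1 modified clone, recovered 38.8% and 71.2%. The total test recovered 97.0% and 98.5% for Chen2008-1, and 92.3% and 100% for the Chen2008-25 KO clones. The unmodified 129 allele test of Chen2008-1 recovered 90.3% and 98.4%. False calls were at most 2.44% of the calls in any of these. The simulated counts had a common spread for all genes and held no shift between the clone sets. That share therefore does not cover calls that arise from such a shift. With 200 genes changed, the Benjamini-Hochberg threshold is also easier to pass than where few genes change. In the real cis tests 4 of 448 and 6 of 445 genes passed, so the cis recoveries above may be too high for them.

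Alternatives were DESeq2, voom, limma on log2 ratios with pseudocounts of 0.5, 1 or 5, other normalizations, other filters, KO clones included in the cis fit, deletions on 129 or on CAST alone, exact permutation of genotypes and leaving out each clone. Set tests used camera and fry from limma. Alternatives added after the data were seen were halved counts, a fit with no control clones, thinning to the shallowest clone, leaving Trim28 out of library sizes, leaving out control clones, KO clones as the only controls, and the ratio between the clone sets. The comparison of each allele in KO and heterozygous clones was also added then.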

Results

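The data describe how deletion of an enhancer on 1 or both chromosomes changed the RNA of nearby genes in F1 hybrid mouse embryonic stem cells. The design is a cis-trans test: a heterozygous deletion leaves a modified and an unmodified chromosome in the same nucleus, and reads are assigned to the 129 or the CAST copy. There were 8 Chen2008-1 clones (6 deleted on CAST, 2 deleted on 129) and 6 Chen2008-25 clones (5 deleted on both chromosomes, 1 deleted on 129). Depth ran from 135881 to 1331960 allelic reads per clone in the Chen2008-1 set and from 239430 to 891466 in the Chen2008-25 set. The shallowest clone was D10, 1 of the 2 Chen2008-1 clones deleted on 129.

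In clones with the Chen2008-1 deletion, 4 neighbouring genes of chromosome 7 gave less RNA from the modified than from the unmodified chromosome. Zbtb45, which encodes a zinc-finger protein with a BTB domain, kept 33.4% of the RNA of the unmodified copy (95% interval 31.8 to 35.1%). Trim28, which encodes a co-repressor that silences retroelements in embryonic stem cells, kept 46.2% (44.5 to 47.9%). Ube2m, the conjugating enzyme for NEDD8, kept 80.6% (74.7 to 87.0%), and the zinc-finger gene Zfp446 kept 77.7% (69.6 to 86.7%). The log2 effects were -1.58 for Zbtb45 (SE 0.03, edgeR adjusted p = 1.03e-19), -1.12 for Trim28 (SE 0.03, adjusted p = 2.06e-19), -0.31 for Ube2m (SE 0.05, adjusted p = 0.00115) and -0.36 for Zfp446 (SE 0.08, adjusted p = 0.0115).

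The allelic shares moved in opposite directions in the clones deleted on either chromosome. The 129 share of Zbtb45 was 72.2% ± 1.53 (SD, n = 6) in clones deleted on CAST and 22.3% ± 0.262 (SD, n = 2) in clones deleted on 129. It was 47.3% ± 1.39 (SD, n = 6) in the Chen2008-25 clones. For Trim28 the shares were 67.5% ± 1.53 (SD, n = 6), 30.2% ± 1.62 (SD, n = 2) and 49.9% ± 0.583 (SD, n = 6) in the same order. For Ube2m they were 58.4% ± 1.94, 48.6% ± 1.29 and 52.8% ± 2.05, and for Zfp446 46.1% ± 3.20, 34.8% ± 2.14 and 39.1% ± 3.34. Trim28 and Zbtb45 lie on opposite strands with overlapping spans but share 0 exonic bases in the annotation, and whether the counting used strand is not given in the sources used here.

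**Figure D1:**
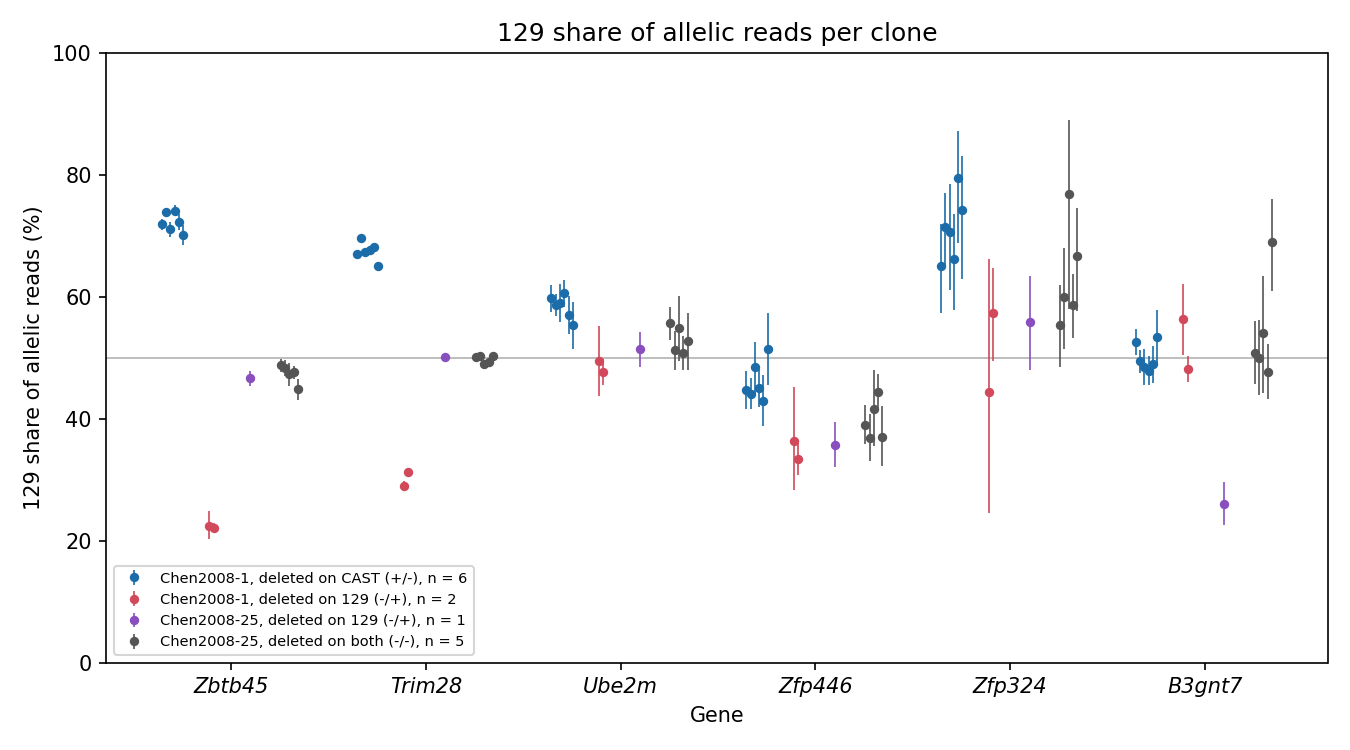
The 129 share of allelic reads in percent (vertical axis) is plotted for 6 genes (horizontal axis), with a point for each clone, its 95% Wilson interval and a colour for each enhancer and genotype. Zbtb45 lies near 72.2% in clones deleted on CAST, near 22.3% in clones deleted on 129 and near 47.3% in the Chen2008-25 clones, and B3gnt7 is at 26.0% in the single Chen2008-25 clone deleted on 129.

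These 4 genes were all of the cis calls among 448 genes tested, and 27 genes had an unadjusted p under 0.05. All 4 lie in a run of 20 neighbouring panel genes on chromosome 7, 19 of them tested, and 17 of the 19 had a negative estimate. The run was chosen after its values were seen. Zfp324, next to Zfp446, had the next smallest p with an estimate of -0.55 (SE 0.16, adjusted p = 0.227), and Mzf1, next to Ube2m, was at -0.36 (SE 0.15, adjusted p = 0.666). The DNA ligase gene Lig1, further along the run, was at -0.03 with an interval of -0.10 to 0.03. Leaving out clone D2, which leaves D10 as the only clone deleted on 129, gave 15 calls. The count was 27 with deletions on 129 alone and 56 with deletions on CAST alone. Zfp324 passed with a pseudocount of 5 in limma (-0.55, adjusted p = 0.0401) and with deletions on CAST alone (-0.67, adjusted p = 0.0477), and Lig1 passed with deletions on CAST alone (-0.13, SE 0.03, adjusted p = 0.0111). With deletions on CAST alone, a ratio shift between the clone sets is not balanced by the other direction. Passing in that fit is therefore no evidence of a cis effect by itself.

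**Figure D2:**
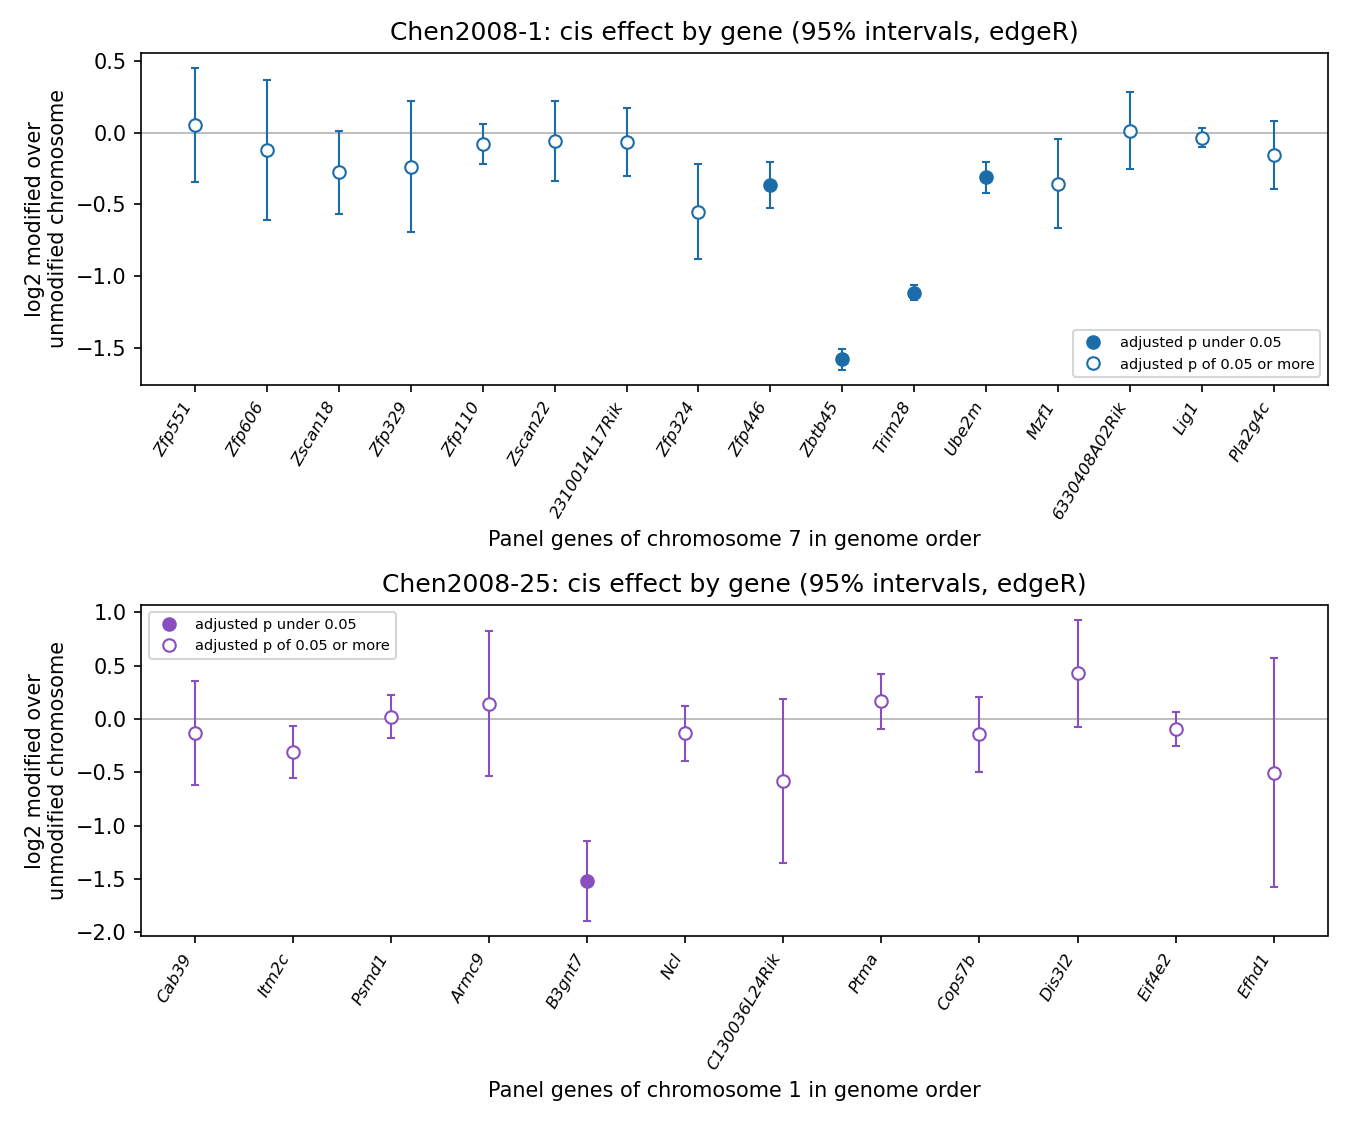
The log2 change of the modified over the unmodified chromosome (vertical axis) is plotted for the panel genes reported here that had a mean of at least 50 reads, in genome order (horizontal axis), for the chromosome 7 run in Chen2008-1 clones (top) and the chromosome 1 run in Chen2008-25 clones (bottom). Bars are 95% intervals and filled points have an adjusted p under 0.05; Zbtb45 is at -1.58 and Trim28 at -1.12 in the top panel, and B3gnt7 at -1.52 in the bottom panel.

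Clones deleted on either parental chromosome were made to control for haplotype effects. Zbtb45 fell by 1.65 on the log2 scale (SE 0.06) where 129 was deleted and by 1.54 (SE 0.05) where CAST was deleted. Trim28 fell by 1.20 (SE 0.03) and 1.06 (SE 0.03) in the same order. The difference between backgrounds was -0.11 for Zbtb45 (interval -0.30 to 0.08, edgeR adjusted p = 0.582) and -0.13 for Trim28 (interval -0.27 to -0.00305, adjusted p = 0.241). Ube2m was at -0.26 (SE 0.13) with deletions on 129 and -0.35 (SE 0.08) with deletions on CAST, and Zfp446 at -0.32 (SE 0.18) and -0.39 (SE 0.11). Both had an adjusted p above the threshold with the 2 clones deleted on 129 alone (0.407 for Ube2m and 0.510 for Zfp446), and the differences were 0.09 (interval -0.24 to 0.43) and 0.07 (interval -0.41 to 0.54). Across the panel 51 of 448 genes differed between backgrounds, and none of these 4 was among them. All controls for this contrast were Chen2008-25 clones, so a shift in allelic ratio between the clone sets enters it with opposite sign in each background. The orphan receptor gene Gpr19 was at -0.74 (SE 0.12) with deletions on 129 and 0.74 (SE 0.07) with deletions on CAST. For Chen2008-25 this comparison could not be fitted, since no clone was deleted on CAST alone.

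On the unmodified chromosome, Trim28 stayed near the level of the Chen2008-25 clones. Its unmodified 129 allele was at a log2 difference of -0.02 (SE 0.12, edgeR adjusted p = 0.919) and its unmodified CAST allele at 0.15 (SE 0.20, adjusted p = 0.584). The unmodified allele of Zbtb45 was higher, by 0.45 on 129 (SE 0.06, adjusted p = 2.21e-06) and 0.54 on CAST (SE 0.09, adjusted p = 0.000236). That of Ube2m was higher by 0.46 on 129 (SE 0.09, adjusted p = 0.00023) and 0.50 on CAST (SE 0.12, adjusted p = 0.00401). Zfp446 was at 0.07 (SE 0.09) on 129 and -0.06 (SE 0.14) on CAST. The modified allele of Zbtb45 was at -1.10 (129) and -1.09 (CAST) against the same allele of the controls, and that of Trim28 at -1.07 on both. That of Zfp446 was at -0.35 (129, SE 0.14) and -0.32 (CAST, SE 0.10). The modified allele of Ube2m was not lower than in the controls, at 0.26 (129, SE 0.13, adjusted p = 0.135) and 0.12 (CAST, SE 0.09, adjusted p = 0.231). The Zbtb45 value on the unmodified 129 allele lay at percentile 77.9 of all genes tested, so differences of that size between the clone sets were common.

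Many panel genes differed on the unmodified allele, also away from chromosome 7, and the counts here are over all chromosomes. Of 412 genes, 221 passed on the 129 allele (122 higher, 99 lower), and of 395 genes, 146 passed on the CAST allele (90 higher, 56 lower). The lactate transporter gene Slc16a3 was higher by 3.76 (SE 0.25) on 129 and 3.17 (SE 0.33) on CAST. Pycr1, an enzyme of proline synthesis, was higher by 1.24 (SE 0.09) and 1.23 (SE 0.14). On 129, Fam195b was higher by 1.06 (SE 0.07), the hormone receptor gene Amhr2 by 1.83 (SE 0.14) and B3gnt7, the gene that was lower in the Chen2008-25 clones (the controls here), by 1.99 (SE 0.12). On CAST, Hps4 was higher by 1.11 (SE 0.13), while the RNA-binding protein gene Hnrnph1 fell by 0.79 (SE 0.09) and the acetyl-CoA carboxylase gene Acacb fell by 1.48 (SE 0.17). The adjusted p of these named genes was at most 7.94e-06. The CAST count rests on both clones deleted on 129: it was 97 without D10 and 90 without D2. These contrasts compare Chen2008-1 with Chen2008-25 clones, so enhancer and clone set cannot be told apart.

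Summed over both alleles, Trim28 in the Chen2008-1 clones was at 74.8% of its level in the Chen2008-25 clones (log2 -0.42, SE 0.12, edgeR adjusted p = 0.00486). Zbtb45 was at 91.8% (log2 -0.12, SE 0.05, adjusted p = 0.0518) and Zfp446 at 89.8% (log2 -0.15, SE 0.07, adjusted p = 0.0518), both above the threshold. Ube2m was at 126% (log2 0.33, SE 0.07, adjusted p = 0.000762). Of 448 genes, 287 passed, 151 higher and 136 lower. The smallest p-values were those of Pycr1 (1.29, SE 0.08, adjusted p = 1.88e-09), Acacb (-1.34, SE 0.09), Fam195b (1.01, SE 0.07), Slc16a3 (3.62, SE 0.26) and Hnrnph1 (-0.75, SE 0.05, adjusted p = 2.57e-09).

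B3gnt7 on chromosome 1, the gene of an N-acetylglucosaminyltransferase of keratan sulfate synthesis, was lower in clones with the Chen2008-25 deletion. In the KO clones its total was at 23.4% of the Chen2008-1 clones (log2 -2.09, SE 0.11, edgeR adjusted p = 7.07e-11), and in the heterozygous clone E6 at 48.8% (log2 -1.03, SE 0.19, adjusted p = 0.000657). The normalised total level was 451 CPM ± 25.5 (SD, n = 5) in KO clones, 943 CPM in E6 and 1935 CPM ± 277 (SD, n = 8) in the Chen2008-1 clones. Within E6 the modified 129 chromosome gave 34.9% of the RNA of the unmodified one (95% interval 26.8 to 45.3%, log2 -1.52, SE 0.18, adjusted p = 0.000241). The 129 share in E6 was 26.0% (149 of 574 reads, Wilson interval 22.5 to 29.7%), against 50.6% ± 3.07 (SD, n = 8) in the Chen2008-1 clones and 54.3% ± 8.52 (SD, n = 5) in the KO clones.

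The levels of the separate alleles of B3gnt7 were also used to check the order in which the genotypes were read, so they are no independent test of it. In KO clones the 129 copy was at -2.01 (SE 0.13) and the CAST copy at -2.18 (SE 0.14) against the Chen2008-1 clones. In E6 the modified 129 copy was at -1.99 (SE 0.25, edgeR adjusted p = 3.27e-05), and the unmodified CAST copy at -0.46 (SE 0.23, interval -0.94 to 0.03, adjusted p = 0.139). Between KO clones and E6, B3gnt7 on the CAST copy was the 1 gene that passed (-1.72, SE 0.22, adjusted p = 0.000143). Its 129 copy was at -0.02 (SE 0.24, interval -0.52 to 0.48). The cis effect in E6 has no replicate clone: with 1 clone among 9, the exact permutation of genotypes cannot give a p below 0.111. In the chromosome 1 run of 20 panel genes, 17 were tested and B3gnt7 was the 1 called. Its neighbour Ncl, which encodes nucleolin, was at -0.13 (interval -0.39 to 0.12) and Armc9, on the other side, at 0.14 (interval -0.54 to 0.83). Itm2c, further along the run, was at -0.31 (interval -0.55 to -0.07). Of the 17 tested genes 10 had a negative estimate, B3gnt7 among them. With 1 modified clone, small changes of the neighbours can be missed. A ratio also cannot show a change common to both copies. Against the Chen2008-1 clones, Ncl was higher in KO clones by 0.90 (129, SE 0.08) and 0.90 (CAST, SE 0.09). In E6 it was higher by 0.92 and 1.06. Armc9 in KO clones was at 0.01 (129, SE 0.14) and -0.43 (CAST, SE 0.17). Enhancer and clone set cannot be told apart in these levels.

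**Figure D3:**
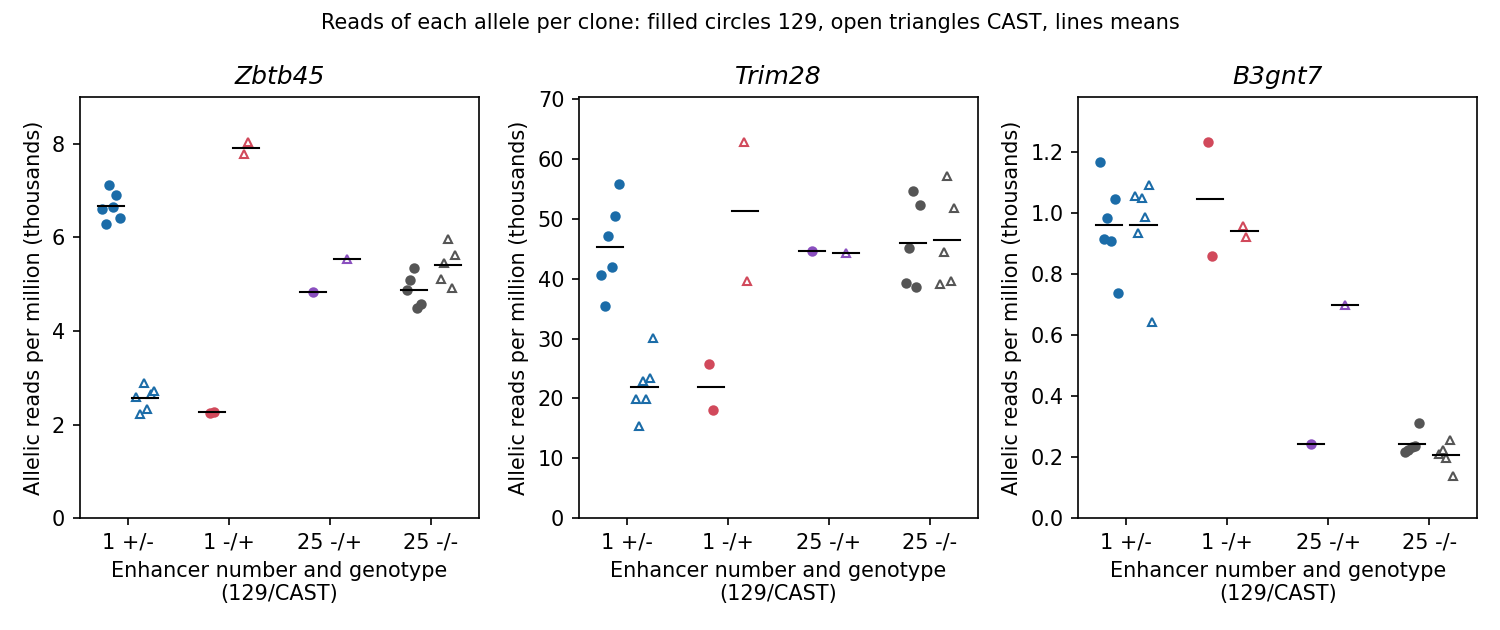
Normalised allelic read levels (vertical axis, in kCPM) are plotted for Zbtb45, Trim28 and B3gnt7 by enhancer and genotype (horizontal axis), with filled circles for 129, open triangles for CAST, a point per clone and lines for means. In E6 (25 -/+) the 129 copy of B3gnt7 is at 245 CPM and the CAST copy at 698 CPM, and in the KO clones the means are 244 and 206 CPM.

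Away from chromosome 1, 5 further genes passed the cis test in E6. Bahcc1 (0.75, SE 0.13, edgeR adjusted p = 0.00949), Ly6e (0.77, SE 0.14, adjusted p = 0.0121), Gpr19 (0.75, SE 0.15, adjusted p = 0.0237) and the pore-forming gasdermin gene Gsdmd (1.06, SE 0.24, adjusted p = 0.0373) had a higher share from the 129 allele. Gprc5a, another orphan receptor gene, had a lower one (-0.68, SE 0.14, adjusted p = 0.0237). They lie on chromosomes 11 (Bahcc1), 15 (Ly6e and Gsdmd) and 6 (Gpr19 and Gprc5a). Altogether 6 of 445 genes passed, and 47 had an unadjusted p under 0.05. The count was 14 in DESeq2 and 3 in limma with a pseudocount of 1. With KO clones included as controls 1 gene passed, B3gnt7 (-1.57, SE 0.26, adjusted p = 0.00522). With KO clones as the only controls, B3gnt7 again was the 1 gene that passed (-1.69, SE 0.32, adjusted p = 0.00228), and Gprc5a changed sign (0.53, adjusted p = 0.696). The 129 share of Gpr19 was 61.9% in E6, 61.3% ± 2.83 (SD, n = 5) in KO clones and 48.7% ± 3.32 (SD, n = 8) in Chen2008-1 clones.

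On the unmodified CAST allele of E6, 109 of 402 genes passed (50 higher, 59 lower). Acacb was higher by 1.47 (SE 0.18, edgeR adjusted p = 0.000429), Hnrnph1 by 0.84 (SE 0.10, adjusted p = 0.000429) and the chromatin remodeller gene Chd2 by 1.01 (SE 0.15, adjusted p = 0.000934). The heme-binding protein gene Hebp1 fell by 1.47 (SE 0.20, adjusted p = 0.000635) and Bahcc1 fell by 1.95 (SE 0.28, adjusted p = 0.000934). B3gnt7 on this allele was at -0.45 (SE 0.21, adjusted p = 0.134) in the same fit. E6 is a single clone, assumed here and in its totals to vary like the clones of the other groups. Enhancer and clone set cannot be told apart in this contrast.

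In totals, 277 of 448 genes passed in the KO clones (131 higher, 146 lower) and 158 in E6 (75 higher, 83 lower). In the KO clones the smallest p-values after that of B3gnt7 were those of Pycr1 (-1.30, SE 0.09, edgeR adjusted p = 6.76e-09), Acacb (1.34, SE 0.09), Fam195b (-1.02, SE 0.07) and Utp6 (0.72, SE 0.05). E6 differed in the X-linked genes Phka1 (1.58, SE 0.19) and C77370 (1.21, SE 0.15), in Acacb (1.29, SE 0.16), Hnrnph1 (0.81, SE 0.10) and Trnau1ap (-0.87, SE 0.11), with an adjusted p of at most 2.71e-05. KO clones and E6 shared 151 called genes, all in the same direction. Independent lists of these sizes would share 49.0 genes in the same direction. In 20 simulations with no effect and the same controls, 0 were shared on average. With no effect few genes can pass at all, so the simulations cannot show how far common controls raise the overlap. With the 8 control clones parted into sets of 4, 1 for each comparison, the calls shared in the same direction were 71 or 144. These contrasts use the same clones as the Chen2008-1 total contrast with the sign reversed, so enhancer and clone set cannot be told apart here either.

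The 5 measured members of the X-linked list moved both ways in the KO clones. Rlim, a ubiquitin ligase gene, rose by 0.52 (SE 0.08) and Chic1 by 1.15 (SE 0.17). Xist fell by 0.47 (SE 0.18), its antisense partner Tsix fell by 0.58 (SE 0.17) and Cdx4 fell by 1.03 (SE 0.31). These 2 rises and 3 falls passed over all genes tested and adjusted over the list alone. The list as a set did not pass in camera (p = 0.655, p = 0.727 with an estimated correlation) or fry (p = 0.289), and its median of -0.47 had the opposite sign to camera's direction. In E6 the rises of Rlim (0.70, SE 0.15) and Chic1 (1.37, SE 0.29) passed and the other 3 members did not, with a median of -0.49, again opposite to camera's direction, a camera p of 0.363, a p of 0.485 with an estimated correlation and a fry p of 0.105. Xist and Tsix overlap on opposite strands, so their reads can be told apart only if the counting used strand. Rprd1b and 2010009K17Rik, which overlap by 100% on opposite strands, had nearly the same reads over all clones (15913 and 15899). Counting without strand would give this, though it is a single pair. Other pairs with that overlap differed in reads, Xist and Tsix among them (2588 and 4561). Overlapping spans need not share exons, and shared exons were not looked at for these pairs. The falls of Xist and Tsix may rest in part on the same reads, which these counts cannot settle.

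The median 129 share of 434 autosomal genes was 50.6%, with the genes called near each deletion read in the clones of the other enhancer alone, and the median SD over clones was 4.74 percentage points. In 39 genes the mean 129 share was above 2/3 and in 41 it was below 1/3, together 18.4% of the genes. A shift of B3gnt7 to 26.0% or of Zbtb45 to 22.3% was several times the median SD between clones.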

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

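The tests on the 5 genes of clone E6 and the comparison of allelic ratios between the clone sets were chosen after the result was seen, as were thinning and leaving out Trim28, whose limits were set before they were run.

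In the groups of 6 +/- and 5 KO clones, 72 tests for a clone far from its group gave 5 hits, and chance gives about 1 in 20. The 129 share of Bahcc1 was 73.1% in KO clone G2, with the others from 59.8 to 63.2%. Clone H7 had a 129 share of 65.9% for Ly6e (others 56.9 to 60.2%), 32.6% for Gprc5a (others 38.2 to 41.4%), and a Zfp446 total of 9.65 log2 CPM (others 9.95 to 10.09). KO clone H4 had a Gprc5a total of 12.24 log2 CPM (others 12.37 to 12.41). Between deletions on 129 and on CAST, 51 genes of Chen2008-1 clones differed in a test of the difference, and all 41 genes whose allelic ratio differed between KO and Chen2008-1 clones were among them. The contrasts share clones, and a ratio shift between the clone sets enters both, so this overlap is not independent evidence. The 51 genes therefore need not depend on which chromosome was deleted. The count of 41 fell to 23 without clone D2.

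Away from B3gnt7 on chromosome 1, 5 genes shifted in ratio in E6: Bahcc1 on chromosome 11, Ly6e and Gsdmd on 15, and Gpr19 and Gprc5a on 6. A cis effect of a deletion near B3gnt7 is argued against by these chromosomes, and by the KO clones, which lack the enhancer on both copies and had a median of 0.838 of the shift in E6, with 4 of the 5 genes passing in the same direction. The KO shift of Bahcc1 did not pass (0.29, SE 0.10, adjusted p = 0.075) but did without clone B4 (0.36, adjusted p = 0.0382), and that of Gsdmd passed (0.72, SE 0.18, adjusted p = 0.00521) but not without D2 (0.84, adjusted p = 0.102) or H2 (0.57, adjusted p = 0.0502). Both comparisons used the same 8 control clones, and with these parted into sets of 4 the median was 0.749 with one parting and above 1 with the other, again with 4 genes passing. A difference between the clone sets is a candidate explanation for those 4, of untested origin.

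Totals of 287 of 448 genes differed between the clone sets. Library size as the whole cause is argued against by thinning every clone to 135881 reads, after which 222 genes passed, against 287 before. The share of reads taken by Trim28 is argued against by leaving it out, with 288 calls. Clone derivation or culture cannot be told apart from the enhancer, because 0 of the numbers in the column headers occur in both sets, while a number common to all sample titles has no meaning given in the sources used here. An effect of the deletions on these genes stays open as well, untested.

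Other splits of the clones did not give as many calls. For Chen2008-1 totals 1 of 100 splits, the real one, reached 287, and the highest of the others gave 183. The smaller side of that split held 6 Chen2008-1 clones, so it was nearly the real split turned round. For the KO totals the real 277 stood against at most 83, for the unmodified 129 allele of Chen2008-1 221 against 116, for the Chen2008-1 cis effect 4 against 2, and for the ratio between clone sets 41 against 11, each 1 of 100. The smallest share that 100 splits can give is 1 in 100, so chance is unlikely for these counts but not excluded. A structure shared by a clone set is not excluded by them either.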

How the results depend on the processing

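Leaving out control clones, halving counts, thinning, leaving out Trim28, the fit with no control clones, KO clones as the only controls and the ratio between clone sets were chosen after the data were seen. Zbtb45 and Trim28 kept their direction and passed in all 26 alternatives of the cis test (log2 -1.65 to -1.54 and -1.20 to -1.06), among them the fit of Chen2008-1 clones with no controls. The Chen2008-1 cis count was 27 with deletions on 129 alone and 56 with deletions on CAST alone, where the shift between clone sets is no longer balanced by the other direction. It ranged from 4 to 15 with 1 clone left out. The Chen2008-25 cis count of 6 was 14 in DESeq2, 3 in limma with a pseudocount of 1 or 5, and 1 with KO clones included or as the only controls, with Gprc5a reversed at 0.53 in the latter. It was 0 by exact permutation, where 9 assignments allow no p under 0.111, and 4 to 9 with 1 clone left out. B3gnt7 kept its direction in 19 alternatives (-1.69 to -1.49) and passed in 18, all but that permutation, with adjusted p from 2.24e-13 to 0.706. The cause of the other changes was not tested.

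With 1 clone left out, calls ranged from 90 to 153 (CAST) and 209 to 232 (129) on the unmodified allele of Chen2008-1, 83 to 124 on that of E6, 271 to 289, 261 to 284 and 148 to 169 in totals of Chen2008-1, KO and E6, and 23 to 45 for the ratio between sets. No other setting moved these counts, or the share of skewed autosomal genes, by over 1.5 times. Of the values of named genes, 265 kept direction and side of the threshold over settings, 28 no longer passed, 2 newly passed and 1 reversed. With 1 clone left out, 559 kept both, 8 no longer passed and 1 newly passed. Clones without either deletion, a Chen2008-1 KO and a Chen2008-25 clone deleted on CAST alone were not among the samples, and E6 cannot be left out, so those alternatives were not run. Taking clones of the other enhancer as the controls is the design reported.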

Other observations

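The tests on chromosome X were chosen after the result was seen. The X genes of the panel were read almost only from 129. In 13 of 14 genes fewer than 5% of reads were CAST, pooled 0.631%, from 0.375% to 1.54% per clone. Failed assignment of CAST reads gene by gene is argued against by the 4 of 434 autosomal genes under the same limit (Fisher's exact test, two-sided, p = 8.37e-21). Random loss or silencing of either X in separate clones is argued against by all 14 clones lacking the same copy, which has a probability of 0.000122 under that explanation. Loss or silencing of the CAST X in the parental line may explain this for those 13 genes and was not tested. Silencing driven by Xist would need Xist RNA from the CAST X, and no sign of it was seen: Xist had 2572 reads of 129 and 16 of CAST.

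Totals of X genes differed between the clone sets in 11 of 14 genes. In the Chen2008-1 clones 8 were lower, led by Gm9112 (-2.94, SE 0.32), Dmrtc1b (-2.14, SE 0.37) and Phka1 (-1.34, SE 0.11), and 3 were higher: Xist (0.47, SE 0.17), Tsix (0.56, SE 0.16) and Cdx4 (0.97, SE 0.28). Xist and Tsix overlap and may share reads. The median of the 14 genes, -0.72, was below that of every other chromosome, the next being chromosome 10 with 4 genes at -0.65. Among genes with high totals in the Chen2008-1 clones were those of the paired keratins Krt8 (2.36, SE 0.19) and Krt18 (1.57, SE 0.34), with the cell cycle inhibitor gene Cdkn1b (0.71, SE 0.07) and Myc (0.80, SE 0.14). Lower genes were those of nucleolin, Ncl (-0.92, SE 0.08), and of the heterochromatin protein Cbx5 (-0.94, SE 0.08). These genes were chosen after their values were seen, and enhancer and clone set are confounded for them.

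The allelic ratio of Krt8 differed between the sets too, with a mean 129 share of 61.4% in KO clones and 78.6% in Chen2008-1 clones (log2 ratio -1.26, SE 0.16, adjusted p = 8.52e-07). Whole-chromosome imbalance of single clones was looked for in the 7 autosomes with at least 20 genes, after each gene's median over the clones was subtracted. The median shift of the log2 ratio in a clone lay between -0.28 and 0.18. Both ends came from chromosome 7, which holds the genes called in the Chen2008-1 cis test. In the other autosomes looked at, it lay between -0.08 (chromosome 5) and 0.16 (chromosome 1). An imbalance common to most clones, or on another chromosome, would not show in these values.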
